A study of Rattus norvegicus with 4 samples.

How the data were processed

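MicroRNAs were measured in PC12 cells, a line from a rat adrenal pheochromocytoma that grows neurites under nerve growth factor (NGF). The labels give 4 samples, 1 for each of 0, 12, 24 and 48 h in 100 ng/ml NGF, each hybridised to its own one-colour (Cy3) Agilent rat miRNA array from 100 ng of total RNA. Per the labels' protocols, cells were grown in medium with 10% horse serum and 5% fetal bovine serum and treated in medium with 1% and 0.5% of these. The labels do not say in which medium the 0 h cells were collected.

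The deposited array files hold spot intensity values on a linear scale, background-subtracted by Agilent Feature Extraction 9.5.3.1 per the file headers. The same tool is named in the submitters' processing notes. The authors also deposited a value table on a log2 scale. Its values, set against the array files, were the log2 of Agilent's total signal per miRNA minus a constant for each array, between 8.66 and 9.03. Between 98 and 104 miRNAs per array lay within 0.01 of that constant, and the reason for the offset of the others stayed unknown, as did the source of the constant. Undetected miRNAs stood in that table at a signal of 0.1, which held for 211, 212, 211 and 216 of 350 miRNAs at 0, 12, 24 and 48 h and made the column medians -12.35, -12.10, -12.11 and -11.98. Names matched for 349 of the 350 miRNAs. This table served as an alternative, not as the main values.

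From the array files, the processed signal of miRNA spots without outlier flags was averaged per probe, divided by the array's 75th percentile over the 218 probes detected on all 4 arrays, and taken to log2. A probe counted as detected when at least 50% of its used spots were well above background, and a miRNA when any of its probes was. The change of a miRNA was the mean over its distinct probes detected on both arrays, and its error is the SD over those probes, which covers variation within an array only. A miRNA counted as higher or lower when it differed by 2-fold or more with all probes in 1 direction. For a miRNA detected on only 1 of a pair of arrays, an at-least fold was taken against the higher of the dim array's lowest detected probe signal and the probe's own signal. Such a fold takes no account of spot noise, and only that of miR-221 was run under the alternatives.

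With 1 array per time there was no test of a single time against 0 h. As a secondary test, limma 3.58.1 in R 4.3.3 set the 3 NGF arrays against the 0 h array over 121 miRNAs, with 2 residual degrees of freedom and Benjamini-Hochberg adjustment at 0.05. That test takes the lone 0 h array to vary like the others and counts differences between NGF times as spread. Lists of miRNAs with at least 3 members detected on both arrays were described by the percentile of their median change among 10000 random lists of the same size, matched on level in 5 classes, and called outside below 2.5 or above 97.5. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

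Groups, tests, lists, alternatives and the rule for named miRNAs were fixed before the data were examined. The rule named miR-221 and miR-222, up to 10 miRNAs in each direction past 2-fold at each time, up to 5 in each direction detected on only 1 array of a pair, the members with the largest and smallest 48 h change of each list, and the 5 highest miRNAs at 0 h. Other miRNAs named below were chosen after their values were seen. Alternatives were scaling over all probes, median, quantile or no scaling, normexp background correction with an offset of 50, Agilent's total signal per miRNA, the deposited table, the median over probes, the brightest probe, outlier spots kept, stricter detection, detection on all 4 arrays, other fold thresholds, arrays left out of the limma test, a linear trend with hours in limma (also with 2 residual degrees of freedom), and the mean of a list. Normexp used the median spot signal because the mean signal is not a column of these files. After seeing the data, normexp without the offset and the processed signal plus 50 were added, to tell the correction from its offset.

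The steps were tested on simulated data for the 48 h comparison, over 129 miRNAs and 20 runs each with 0, 12, 30 or 60 changed miRNAs. All 3-fold changes were called, and none of 1.5-fold or less. No fold between 1.5 and 3 was simulated. The runs therefore do not show how often a change near the 2-fold threshold, such as that of rno-miR-210 at 48 h, would be called. Each run compared all 129 miRNAs, the number detected at 0 h, so loss of detection on an array was not tested. The error left after removing an offset common to all miRNAs averaged 0.048, 0.047, 0.046 and 0.047 log2. The common offset ran from -0.05 to 0.10 with 0 changed miRNAs, -0.20 to 0.15 with 12, -0.22 to 0.26 with 30 and -0.27 to 0.14 with 60, where its mean was -0.10. The scaling factors were also given bootstrap intervals over miRNAs with 1000 draws, a step chosen after the simulations were seen. In a simulation of the limma test on 121 miRNAs with an array SD of 0.15 log2, 40 of 40 miRNAs changed by 1 log2 were called and 1 unchanged one. No measured estimate reached 1 log2 in the main limma test, and smaller changes were not simulated for it.

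The number of arrays limits the precision. All 4 arrays lay on 1 slide, in time order by position, so position and time cannot be told apart. The grid build of the file headers differed from GRCr8, the assembly of the gene table used here, so no coordinates are given and that table served only to find neighbouring miRNA genes.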

Results

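The series followed miRNA levels in PC12 cells over 0, 12, 24 and 48 h of NGF, with 1 array at each time. Each array carried 7000 miRNA spots for 938 probes and 350 miRNAs. The miRNAs detected numbered 129, 130, 129 and 124 at 0, 12, 24 and 48 h, 121 were detected on all 4 arrays, and 218 on none. The 75th-percentile signal was 464, 404, 412 and 356 array units in the same order. By level at 0 h the 5 highest were rno-miR-23b, rno-let-7a, rno-let-7c, rno-miR-29a and rno-miR-16, at log2 levels of 2.76, 2.68, 2.66, 2.64 and 2.42 relative to the scaling signal, although signals of different probes do not rank abundance between miRNAs. There were no replicates, so a difference between 2 arrays has no replicate check, and the SDs below are over the probes of 1 array pair.

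The series title names miR-221, and its level under NGF was the first question. The rno-miR-221 probe A_26_P00002590 was not well above background at 0 h, with a mean signal of 2.05 ± 1.63 (SD, 10 spots), and was detected at every NGF time. Its signal was 12.5 ± 3.19 at 12 h, 15.7 ± 1.15 at 24 h and 14.8 ± 2.06 at 48 h. With the main scaling the level was at least 1.09-fold, 1.34-fold and 1.45-fold higher at 12, 24 and 48 h than at 0 h. Over the alternatives that gave a bound, these went down to 0.944, which gives no fold, 1.16 and 1.12. Stricter detection, with all used spots well above background, gave no bound at 12 and 48 h. At these times 6 and 7 of 10 spots passed, so miR-221 then counted as detected at 24 h only. The other probe, A_26_P00001505, was not well above background on any array and read -0.0078, 4.99, 6.11 and 6.08. rno-miR-222, which is encoded beside miR-221, was not well above background on any array. Agilent's total for miR-221 was 1.39 with an error of 2.58 at 0 h and 14.3 with an error of 2.75 at 48 h, so the 0 h total lay within its own error of 0. In the authors' log2 table the difference was 99.5-fold, 125-fold and 131-fold, with the 0 h value standing at the 0.1 that the table gives to undetected miRNAs.

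**Figure D1:**
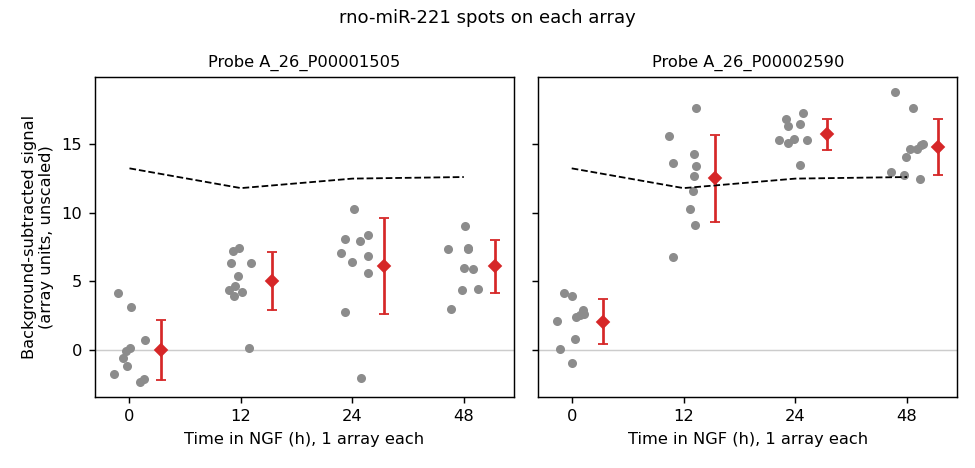
Signal of every used spot (array units, unscaled) of the rno-miR-221 probes on the 0, 12, 24 and 48 h arrays. Dots are spots, diamonds with bars are the mean and SD over spots, and the dashed line joins the lowest detected probe signal of each array. The means of A_26_P00002590 go from 2.05 at 0 h to 12.5, 15.7 and 14.8.

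At 12 h no miRNA was 2-fold higher or lower than at 0 h among 127 compared. The furthest apart were rno-miR-333, at 0.72 log2 on 1 probe, and rno-miR-21, at 0.63. rno-miR-210, a miRNA induced by hypoxia, read -0.57 ± 0.07 (SD, 2 probes), and rno-miR-378 read -0.57. Among miRNAs detected on only 1 of the arrays, rno-miR-674-3p was at least 1.25-fold and rno-miR-351 at least 1.10-fold higher at 12 h. Unscaled, rno-miR-351 read 12.7 at 12 h, under the lowest detected probe signal of 13.2 at 0 h, so its fold depends on the scaling. rno-miR-542-5p and rno-miR-138 were at least 1.13-fold and 1.09-fold lower. Of the 127 miRNAs, 98.4% lay within 1.5-fold of 0 h.

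At 24 h no miRNA passed 2-fold among 126 compared. rno-miR-210 stood at -0.85 ± 0.05 and rno-miR-378 at -0.60. rno-miR-27a read 0.63 ± 0.02, rno-miR-333 0.65 and rno-miR-22 0.57. Of those detected on 1 array, rno-miR-674-3p was at least 1.44-fold and rno-miR-351 at least 1.12-fold higher. Unscaled, rno-miR-351 read 13.1 at 24 h, again under the 13.2 at 0 h. rno-miR-143, abundant in smooth muscle and fibroblasts, was at least 1.39-fold lower, rno-miR-378* 1.19-fold and rno-miR-542-5p 1.09-fold.

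At 48 h, 1 of 122 miRNAs passed 2-fold. rno-miR-210 was lower than at 0 h, with a change of -1.07 ± 0.02 (SD, 2 probes), as its probe signals went from 208 to 77.2 and from 108 to 39.2. The next largest were rno-miR-326 at 0.83 on 1 probe, rno-miR-27a at 0.66 ± 0.05, rno-miR-532-3p at -0.65 on 1 probe, rno-miR-378 at -0.64, rno-miR-181b at 0.63, and rno-miR-22 and rno-miR-333 at 0.61 each. rno-miR-674-3p was at least 1.68-fold higher. rno-miR-30e* was at least 1.32-fold, rno-miR-30c-2* 1.21-fold, rno-miR-143 1.19-fold and rno-miR-378* 1.02-fold lower. Moving only the 48 h scaling factor over its bootstrap interval put the miR-210 change between -1.41 and -0.91. That range holds no variation between arrays, so it is not a confidence interval for the change. The call ended with median scaling, at -0.97, and with normexp, a background correction run on median spot signals with an offset of 50, at -0.53. Normexp without the offset gave -0.89 and the offset without normexp -0.59, both chosen after seeing the data. With normexp and its offset rno-miR-532-3p, rno-miR-378 and rno-miR-326 stood at -0.03, -0.12 and 0.45, against -0.35, -0.45 and 0.72 without the offset. Without scaling the 5 higher miRNAs stood between 0.23 and 0.45.

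**Figure D2:**
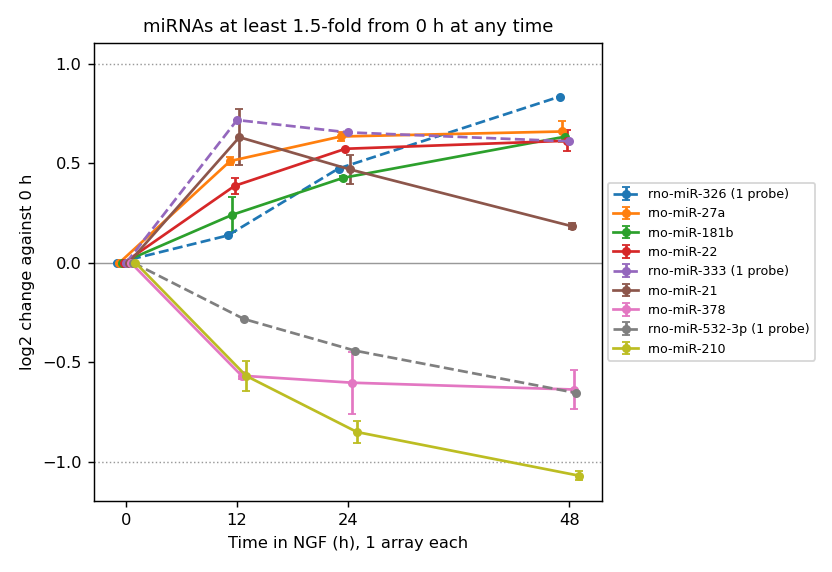
Change in log2 level against 0 h for the 9 miRNAs at least 1.5-fold from 0 h at any time, with bars for the SD over probes and dashed lines for miRNAs measured by 1 probe. Dotted lines mark 2-fold. Only rno-miR-210 passes it, at -1.07 at 48 h.

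Over the time course, 19 of 121 miRNAs had a higher level at each step and 20 a lower level at each step, where chance ordering would give 5.04 in each direction. The split depended on the scaling, with 0 higher and 35 lower without scaling and 28 and 14 with median scaling. It was 26 and 11 with normexp and its offset, 22 and 23 without the offset, and 31 and 12 with the offset alone. Unscaled, 5 bright control probes changed on average by -0.12, -0.15 and -0.25 log2 at 12, 24 and 48 h. The unscaled median miRNA change was -0.26, -0.22 and -0.36, so unscaled falls include some dimming that the control probes share. With the main scaling, those higher at each step included rno-miR-23a, rno-miR-23b, rno-miR-24, rno-miR-27a, rno-miR-22 and rno-miR-181b. Those lower at each step included rno-miR-210, rno-miR-378, rno-miR-25 and rno-let-7i. No miRNA was 2-fold apart in 1 direction at all NGF times, and rno-miR-333, on its 1 detected probe, was 1.5-fold higher at all of them. Unscaled, that probe read 46.0, 65.8, 64.3 and 53.9 at 0, 12, 24 and 48 h. Other probes of rno-miR-333 were not well above background on any array, and the brightest of these read 9.39, 7.96, 7.71 and 8.17. Changes at different times correlated across miRNAs, which are not independent replicates, with r of 0.86 between 12 and 24 h, 0.67 between 12 and 48 h and 0.84 between 24 and 48 h. Unchanged arrays simulated from spot noise against the same 0 h array gave 0.58, 0.54 and 0.52, without any variation between arrays beyond that noise. The covariances were 0.0378, 0.0363 and 0.0547 against simulated ones of 0.00168, 0.00162 and 0.00169. The SD of the changes was 0.19, 0.23 and 0.28 at 12, 24 and 48 h.

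In the limma test of the 3 NGF arrays against the 0 h array, rno-miR-333 (log2 change 0.66, adjusted p = 0.028) and rno-miR-27a (0.60, adjusted p = 0.0448) were higher and rno-miR-378 (-0.60, adjusted p = 0.028) was lower. Each kept its direction at 12, 24 and 48 h, which adds no support, since the test favours like changes against the same 0 h array. With normexp and its offset, not run in limma, rno-miR-333, on its 1 detected probe, read 0.43, 0.39 and 0.41 at these times. Under the same setting rno-miR-378 read -0.16, -0.18 and -0.12 (-0.41, -0.44 and -0.45 without the offset). rno-miR-210 did not pass, at -0.83. Its change went from -0.57 at 12 h to -0.85 and -1.07 at 24 and 48 h, which this test counts as spread. Over the limma runs of NGF arrays against the 0 h array its estimate ran from -1.08 to -0.71. The runs that left out 1 NGF array had 1 residual degree of freedom. Without the 24 h array limma called 0 miRNAs, and without the 12 h or the 48 h array 13 and 18. It also called 0 under quantile normalization, and 0 higher and 11 lower without scaling. A linear trend with hours in limma, run with the main scaling only, called none of these 3. The trend called rno-miR-326, rno-miR-181b and rno-miR-598-3p as rising and rno-miR-532-3p and rno-miR-532-5p as falling, with adjusted p from 0.0279 to 0.0439. On its 1 detected probe rno-miR-326 read 17.5, 16.7, 21.5 and 23.9 unscaled at 0, 12, 24 and 48 h. The lowest detected probe signal at 0 h was 13.2. With normexp and its offset rno-miR-532-3p, also on 1 probe, read 0.02, -0.08 and -0.03 at 12, 24 and 48 h. Without the offset it read -0.11, -0.29 and -0.35.

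The clusters of miR-23, miR-27 and miR-24 were higher relative to random lists of miRNAs. With the main scaling all 5 members had a change above 0 at each time, and the list median was 0.18, 0.32 and 0.41 at 12, 24 and 48 h, at percentiles of 97.515, 98.8 and 98.8 of random lists, while without scaling the medians were -0.02, 0.15 and 0.03. The 12 h percentile fell inside the random range in 4 alternatives, at 95.4 to 97.4. At 48 h the members ran from rno-miR-27b at 0.19 to rno-miR-27a at 0.66. The cluster of miR-17, miR-20a and miR-92a with its paralogs, known for promoting proliferation, had medians of -0.15, -0.19 and -0.22 over 9 members, at percentiles of 0.32, 0.27 and 0.30. The medians of this list were -0.35, -0.37 and -0.60 without scaling, -0.02, -0.05 and -0.04 with normexp and its offset, and -0.09, -0.09 and -0.15 without the offset. At 48 h its percentile came inside the random range with normexp with the offset (2.67) and without it (2.51), Agilent's totals (3.29) and the brightest probe (5.30), and with the offset alone at 12 and 48 h (3.71 and 3.35). rno-miR-25 stood at -0.35 at 48 h and rno-miR-19a, measured by 1 probe, at 0.23. Members of these families are close in sequence and may share signal. The stress, hypoxia and inflammation list, with 2 members above and 2 below 0, had a median of 0.16 and a percentile of 98.1 at 12 h (median -0.04 without scaling), then percentiles of 96.4 and 42.2, with rno-miR-22 at 0.61 and rno-miR-210 at -1.07 at 48 h. By its mean the 12 h percentile was 88.2, inside the random range, and the 24 h percentile lay outside it in 6 alternatives, at 97.51 to 98.8. Of 33 list values over 11 lists and 3 times, 7 lay outside the range of random lists against 1.65 expected. These were the lists of miR-23, miR-27 and miR-24 and of miR-17 and its paralogs at each time, and the stress list at 12 h. The 3 times share the 0 h array and some lists share members. The values are therefore not independent, and 7 against 1.65 is a description, not a test.

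The neuron-enriched list did not stand apart, with medians of -0.11, -0.05 and -0.08 over the 9, 10 and 10 members compared of 24 on the array. Its undetected members, among them rno-miR-124 and rno-miR-137, give no change, so this covers the detected ones only. At 48 h rno-miR-326 at 0.83 and rno-miR-9* at -0.26 stood at its ends. The neuroendocrine list had medians of -0.05, 0.05 and 0.17, the last at a percentile of 95.1, from rno-miR-375 at -0.23 to rno-miR-335 at 0.32. At 48 h the let-7 family had a median of 0.04, with rno-let-7i at -0.32 and rno-let-7b at 0.17. The miR-15/16 family stood at -0.07, with rno-miR-195 at -0.20 and rno-miR-503 at 0.44. The miR-29 family stood at 0.10, from rno-miR-29c at 0.07 to rno-miR-29b at 0.19, and the miR-30 family at -0.05, from rno-miR-30a at -0.12 to rno-miR-30e at 0.07. The miR-181 family stood at -0.02, from rno-miR-181c at -0.16 to rno-miR-181b at 0.63. With the main settings none of these lay outside the random range at any time, but the neuroendocrine list at 48 h did with normexp and its offset, at 98.2. Of the 33 list medians, 11 took the other sign without scaling and 12 with median scaling.

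Some lists had too few detected members for a percentile. rno-miR-132 and rno-miR-212, both regulated by CREB, read 0.23 and -0.12 at 12 h, -0.01 and -0.08 at 24 h, and -0.26 and 0.26 at 48 h. From the X-linked cluster, rno-miR-503 read 0.55, 0.46 and 0.44 and rno-miR-322 read 0.09, 0.16 and 0.16. Of the imprinted clusters 1 member, rno-miR-494, was detected, at 0.19, -0.08 and 0.42. The mesenchymal, muscle, and blood, endothelium and serum lists were set up as markers of other cell types. Yet rno-miR-10a-5p, rno-miR-10b and rno-miR-152 of the mesenchymal list were detected on all arrays, at log2 levels of 0.94, -0.26 and -1.46 at 0 h. That list is therefore not read as a sign of other cells. It had all 4 compared members below 0 at 12 h, with a median of -0.11 and a percentile of 10.7. The percentile of this list went outside the random range with normexp and its offset (1.82), with the offset alone (2.48) and by the mean (2.36). Its medians were 0.03 and 0.06 at 24 and 48 h, at 48 h from rno-miR-152 at -0.16 to rno-miR-10a-5p at 0.16. By the rule of at least 50% of spots, no member of the muscle list or of the blood, endothelium and serum list was detected, nor any of the miR-34 and miR-200 families. Agilent's own flag differed for rno-miR-126, a miRNA of endothelium, which it called detected at 0, 12 and 24 h.

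**Figure D3:**
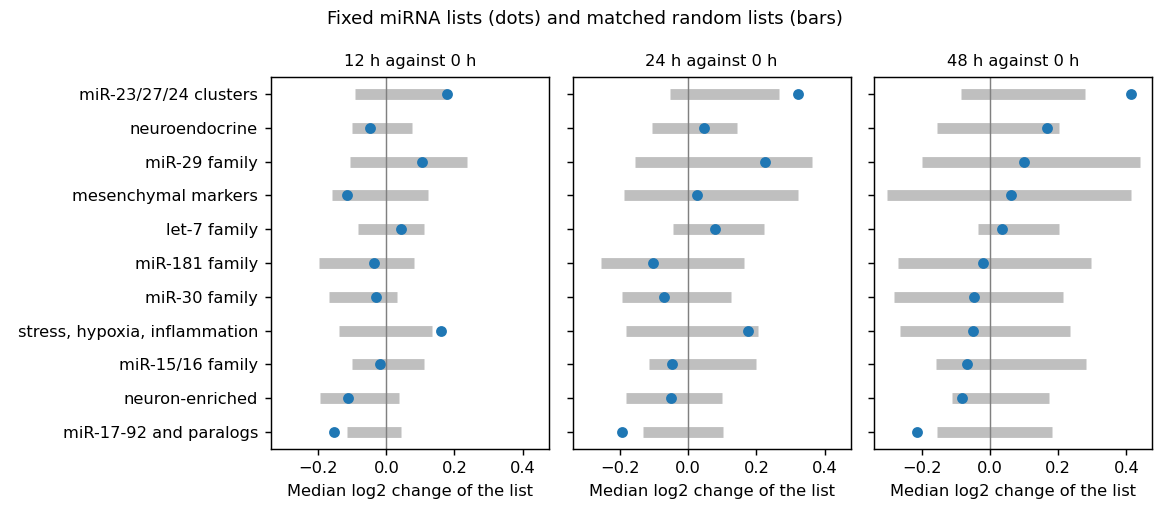
Median log2 change of each list against 0 h (dots) and the range holding the central 95% of matched random lists (bars), at 12, 24 and 48 h. The clusters of miR-23, miR-27 and miR-24 lie above the bar at 24 and 48 h, at 0.32 and 0.41, and the list of miR-17 and its paralogs lies below it at each time.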

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

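Of the tests in this part, those of the floor for undetected miRNAs and of an array-wide background shift were chosen after the result was seen, as was normexp without its offset.

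Changes at 12 h and 48 h had opposite signs for 5 named miRNAs, taken where both changes exceeded the median SD over probes. The 48 h change minus the 12 h change was 0.2487 for rno-miR-10a-5p, -0.4928 for rno-miR-132, 0.5792 for rno-miR-19a, 0.3842 for rno-miR-212 and 0.2073 for rno-miR-30e. These differences were not tested, with 1 array per time, and rno-miR-19a, rno-miR-212 and rno-miR-30e were each measured by 1 probe. The signs were opposite for only 1 of the 5 without scaling (rno-miR-132) and for only 1 with normexp and its offset (rno-miR-10a-5p), but for all 5 with normexp without the offset.

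The 131-fold difference of rno-miR-221 in the authors' log2 table, a log2 change of 7.03 at 48 h, lay 3.669 above the log2 ratio of Agilent's measured totals, but the 0 h total of 1.39 lay within its error of 2.58, so how much the value of 0.1 given to undetected miRNAs adds stays open. The signal itself rose by 12.7 units on the detected probe, while the median of 705 never-detected probes moved by -0.1073 of that rise, which argues against an array-wide background shift. The upper and the lower part of the array both showed it, the smaller rise being 0.8886 of the larger, which argues against an uneven surface. A biological increase of miR-221 under NGF stays a hypothesis of unknown size, and array position, low serum and time in culture are not separated from NGF.

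The lower level of rno-miR-210 at 48 h was weighed against a bias with signal level and against an uneven surface. Its change lay -0.9854 from the median of the 20 miRNAs nearest in level, whose changes ran from -0.53 to 0.45. Because miR-210 was picked as the only miRNA past 2-fold, that gap followed from the choice and does not test the bias. It shows only that miRNAs of like level did not fall alike. The smaller of the falls in the upper and lower part of the array was 0.9053 of the larger, which argues against an uneven surface. The size stays open, at -1.45 to -0.97 over the scalings run, -0.89 with normexp background correction without an offset and -0.53 with normexp and an offset of 50, all of 1 sign. A fall of miR-210 in culture may be biological, but NGF, low serum and time in culture could each be behind it and were not separated.

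The alikeness of changes at 12, 24 and 48 h was weighed against their shared 0 h array. The 0 to 12 h step and the 24 to 48 h step share no array, and their correlation across 121 miRNAs was -0.05074, with a bootstrap interval of -0.25 to 0.15. A deviation of the 0 h array beyond spot noise may therefore account for the alikeness. An early change that then held would give the same value, so a response to NGF also stays open.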

How the results depend on the processing

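The bootstrap of the scaling factors was chosen after the simulations were seen, and normexp without its offset of 50 and the offset alone after the data were seen. That bootstrap put the log2 factor at 48 h between -0.54 and -0.04, and 86.4% of draws left rno-miR-210 at least 2-fold lower. The draws resampled miRNAs on the same arrays, so this share holds no variation between arrays and gives no confidence in the fall. Of 626 values of counts, bounds and lists under alternatives, 578 stayed the same by the rules used. However, 99 of the values are list percentiles that a factor per array cannot move, so these show no stability. The median over probes shows next to none either, since nearly all miRNAs had 1 or 2 detected probes, where median and mean are equal. The same holds for its values among the 440 changes below. Of 33 list medians, 11 took the other sign without scaling, 12 with median scaling, 11 with normexp (4 without its offset, 10 with the offset alone), 10 with quantile normalization and 4 with scaling over all probes. The cause of the shifts that follow was not tested unless stated. The 2-fold counts became 1 at 12 h and 2 at 48 h in the deposited table over miRNAs above its floor on both arrays (rno-miR-219-5p, then rno-miR-210 and rno-miR-378*), where a further 5, 4 and 7 at the floor on 1 array differed by 4.50 to 7.03 log2, and without scaling 1 at 24 h (rno-miR-210) and 3 at 48 h (with rno-miR-378 and rno-miR-532-3p). At 48 h it was 0 with median scaling, normexp with or without its offset, the offset alone and a 3-fold threshold. By construction the 1.5-fold threshold gave 2, 4 and 8, and 1 at all times. The limma count of 3 became 13, 0 and 18 without the 12, 24 and 48 h array, 5 for a linear trend (none of the 3), 11 without scaling (0 higher, 11 lower, 1 of the 3), and 0 with quantile normalization (9 higher and 8 lower at unadjusted p) and with Agilent's totals (7 and 14). With any NGF array as the lone one limma called 0. The miR-221 bound at 12 h was 0.944 without scaling, and stricter detection gave no bound at 12 and 48 h. Agilent's totals, scaled, gave 6.49, 8.03 and 8.92 against the higher of the miR-221 total and the lowest detected total at 0 h. These are not plain ratios of the miR-221 totals. They are read neither as folds nor as firm bounds, since the 0 h total of miR-221 lay within its error of 0. The listed fold was 99.5, 125 and 131 in the deposited table, against its floor. The percentile of the neuroendocrine list at 48 h was 98.2 with normexp. For the list of miR-17 and paralogs at 48 h it was 2.67 with normexp, 2.51 without its offset, 3.35 with the offset alone (3.71 at 12 h), 3.29 with Agilent's totals and 5.30 with the brightest probe. For miR-23, miR-27 and miR-24 at 12 h it was 95.4 with Agilent's totals and with the deposited table, and 97.4 with stricter detection and with detection on all arrays. For the stress list it was 88.2 at 12 h by its mean, and at 24 h 98.1 with quantile normalization, 98.0 with normexp, 98.8 without its offset, 97.51 with the offset alone, 98.5 with outlier spots kept and 97.8 with detection on all arrays. For the mesenchymal list at 12 h it was 1.82 with normexp, 2.48 with the offset alone and 2.36 by its mean. Without scaling, the median of all miRNAs shifted by -0.20, -0.17 and -0.38, with normexp by 0.13 at 12 h, and with the offset alone by 0.10 at 12 h and 0.11 at 48 h. miRNAs with a level at each step higher, or lower, numbered 30 to 45 over 14 alternatives, but from 0 higher and 35 lower without scaling to 31 and 12 with the offset alone. Of 440 changes under alternatives where the reported change was at least 0.3, 5 had the other sign. Signal near background limits dim miRNAs such as miR-221 to bounds. No paired analysis was possible because each time had 1 array.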

Other observations

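All tests in this part were fixed before their result was seen. Outside the lists, the following values at 48 h did not pass 2-fold with the main scaling and are given as values only. rno-miR-598-3p and rno-miR-652 read 0.58 and 0.54 log2, and rno-miR-532-5p stood at -0.53 beside rno-miR-532-3p, the other arm of its hairpin, at -0.65.

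Whether neighbouring miRNA genes changed alike was tested as a hypothesis of transcription from a shared locus. Over 32 neighbouring pairs of different families, the mean absolute difference of the 48 h change was 0.2303 against 0.3003 in permutations, and a share of 0.1067 of 10000 permutations was as low. The bound set beforehand would have counted any share of 0.05 or more against the hypothesis. That bound was badly set, since a difference that misses a threshold over 32 pairs does not show its absence, so the hypothesis stays open.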
